A study of Glycine max with 4 samples.

How the data were processed

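Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on soybean (Glycine max) embryos of the cultivar Williams 82 at mid-maturation, the stage at which the embryo fills with storage reserves. Per the labels' protocols, embryos came from seeds of 200 to 250 mg, were crosslinked for 10 minutes in 1% formaldehyde, and their chromatin was sonicated to 100 to 500 bp. The immunoprecipitation used 2 µg of an antibody raised against a peptide covering amino acids 1 to 15 of the protein encoded by locus GLYMA.13G317000. Libraries were amplified by 15 cycles of PCR, per the labels. The series has 2 ChIP samples and 2 input samples, where input is sonicated chromatin that was not immunoprecipitated. Replicates 1 and 2 carry their numbers in the sample titles, and the series' design text calls them biological replicates.

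The deposited files used here are 1 peak list per ChIP replicate, so peaks were called per sample and not on pooled reads. No file of the input samples was used here. Bowtie 0.12.7, a short-read aligner, and MACS2, a peak caller, are named in the submitters' processing notes. The genome build, the MACS2 version, the calling threshold and the treatment of reads with several alignments are not given in the sources used here. Each deposited peak has a position and a summit, which is the base with the highest read pileup. The deposited fold enrichment is a ratio of the pileup at the summit over a local background. The deposited −log10 p-value and −log10 q-value of each peak are those of MACS2, and the deposited score is the whole-number part of 10 times the −log10 q-value. These values per peak are the authors' own. The largest q-value was 0.00563 in replicate 1 and 0.00871 in replicate 2, so every deposited peak passed the threshold of 0.01 chosen for this work.

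Fold enrichment and p-value together gave back the read numbers behind each peak. In MACS2 the fold is (pileup + 1) / (background + 1), and the p-value is the Poisson chance of a larger pileup. A whole-number pileup that satisfied both to within 0.001 on the −log10 scale was found for 48191 of 48191 peaks in replicate 1 and 62340 of 62340 in replicate 2. On simulated peaks the procedure returned the true pileup in 100% of 4996 cases, and p-values not made by that formula matched a whole pileup in 0.22%. The lowest background, which MACS2 sets from the whole genome, was 2.98 reads in replicate 1 and 2.83 reads in replicate 2. It applied to 27.7% and 23.6% of the peaks, respectively. Higher backgrounds fell on whole multiples of a step of 0.463 reads in replicate 1 and 0.478 reads in replicate 2, or of that step scaled to windows of 1 and 10 kb. The step was taken as 1 read of a control library scaled to the ChIP depth. Within 0.0001 reads, whole multiples were found for 99.9% of raised backgrounds in replicate 1 and for 99.996% in replicate 2, against 0.31% and 0.43% at other steps. That the input samples served as this control is inferred from the design and from these steps. If so, the input libraries were 2.16 and 2.09 times as deep as their ChIP libraries. The shortest peaks, 250 bp and 220 bp, gave the fragment lengths to which reads had been extended. If the same genome size was set for both, replicate 2 held 1.08 times as many ChIP reads as replicate 1. Total read numbers are not given in the sources used here. Pileups at summits ranged from 12 to 316 reads in replicate 1 and from 11 to 332 reads in replicate 2. Intervals made from them cover counting error of the pileup only, since PCR reads without molecular identifiers are not independent molecules. For fold enrichments they take the background as fixed and leave out its own counting error.

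A reproducible peak was a pair of peaks, 1 from each replicate, that were each other's best overlap (at least 1 bp shared) with q of at most 0.01 in both lists. Its position was the midpoint of both summits, and its strength was the geometric mean of both fold enrichments. The overlap of the lists was tested one-sided against 1000 circular shifts of the replicate 1 peaks within each chromosome or scaffold. Chromosome spans were taken as the last peak end on each chromosome, since no genome of the files' build was used. On simulated data the overlap test gave p of at most 0.05 for 8.33% of 60 pairs of independent lists, and recovered an overlap of 51.1% against 2.77% by chance in lists that shared 1000 of 2000 sites. Strengths were compared by Spearman and Pearson correlation across peaks, which are not independent replicates, with a 95% interval from 1000 bootstraps over 994 blocks of 1 Mb. Pileups of both replicates at each shared peak were compared with an exact binomial test after a common scaling, adjusted by the Benjamini-Hochberg method. Their dispersion over counting is the mean squared deviation in units of counting variance, after scaling by the pileup ratio of the peaks at hand. It is 1 where reads are independent and counting error is the only source of spread. With 2 replicates, no p-value here measures the spread between embryo samples. Permutation p-values compare positions or strengths with shifted or permuted ones. The binomial and chi-square p-values take counting error as the only spread, and the sign tests count chromosomes. Shares carry 95% Wilson intervals.

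The definition of reproducible peaks, the overlap test, the comparison of strengths and the rule for named items were fixed before the data were examined. The signed ratio of the replicates' folds, the recovery of read numbers, the comparison of pileups and the comparison of chromosome regions were added afterwards. The rule named the 10 reproducible peaks of highest strength by position if no annotation of the build was at hand. The planned promoter share, motif (G-box) share, bound genes and tests of 16 gene lists needed a genome and annotation of the files' build, and are not reported here. The gene table at hand describes assembly Glycine_max_v4.0. Its positions were not joined to the peaks because the build of the files is not named. The alternatives were no q threshold, q of at most 1e-5, 50% reciprocal overlap, an irreproducible discovery rate of at most 0.05, equal numbers of top peaks, and each replicate alone. The irreproducible discovery rate was computed from a mixture of 2 Gaussian copula components ranked by p. On 20000 simulated pairs, 70% of them reproducible and none cut beforehand, it kept 97.3% of the reproducible ones with a false share of 5.11%. The pairs used here came from lists already cut by q and overlapped, so these rates may not hold for them. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.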

Results

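Sites enriched by the antibody against the protein of locus GLYMA.13G317000 were mapped in mid-maturation soybean embryos. The series has 2 ChIP samples and 2 input samples. It has no other control, and the specificity of the antibody was not tested here. Replicate 1 had 48191 deposited peaks, which covered 22.7 Mb, and replicate 2 had 62340 peaks, which covered 26.3 Mb. Peaks were narrow, with a median width of 421 bp in replicate 1 and 377 bp in replicate 2. The median pileup at a summit was 30 reads in replicate 1, over a median local background of 3.36 reads. In replicate 2 it was 31 reads over 3.31 reads. All coordinates are those of the authors' lists, counted from 1, on a genome build that is not given in the sources used here. Genes at the peaks were not analysed here.

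The first comparison, of immunoprecipitated chromatin with its background, inferred to come from the input samples, asked where in the genome the antibody enriched chromatin. All 20 chromosomes carried peaks. The median fold enrichment over background was 6.77 in replicate 1 and 7.24 in replicate 2, and the highest values were 76.6 and 85.7. In replicate 1, 12856 peaks (26.7%) reached a fold of 10 and 2832 peaks (5.88%) reached 20. In replicate 2, 20103 peaks (32.2%) reached 10 and 5574 (8.94%) reached 20. A fold of 50 was reached by 49 peaks in replicate 1, by 185 in replicate 2, and by 33 reproducible peaks in both.

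The second comparison asked which of these sites were found in both embryo samples. Of the replicate 1 peaks, 93.8% (95% Wilson interval 93.6 to 94.0) overlapped a replicate 2 peak. Of the replicate 2 peaks, 73.3% (72.9 to 73.6) overlapped a replicate 1 peak. Circular shifts of the peaks gave mean overlaps of 5.92% and 4.62%. No shift gave more than 7.83% and 6.13%, so the one-sided permutation p was 0.000999 for both replicates, the smallest that 1000 shifts can give. Shifts of 20 to 100 kb, added after the data were seen to keep the regional density of peaks, raised the chance overlap to 10.4% and 8.15%. Pairs that were each other's best overlap numbered 44959, of which 44720 lay on the chromosomes and 239 on scaffolds. An irreproducible discovery rate of at most 0.05 kept 26117 of these pairs. The rest had passed the q threshold in both lists too, so being left out does not show that they are irreproducible.

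Strong sites were found in both replicates. All 2832 replicate 1 peaks with a fold of 20 or more had a partner in replicate 2, and all 5574 such replicate 2 peaks had a partner in replicate 1. Between a fold of 10 and 20, 1 peak of 10024 in replicate 1 and 56 of 14529 in replicate 2 had none. Below a fold of 4, 2786 of 3616 replicate 1 peaks had a partner (95% Wilson interval 75.6% to 78.4%). In replicate 2 this held for 1626 of 4876 peaks, or 33.3% (32.0 to 34.7). Of the peaks without a partner, 2985 were in replicate 1, with a median fold of 4.43, and 16653 in replicate 2, with a median fold of 4.83. The strongest of them lay on chromosome 10 at 39847500 to 39847844 in replicate 2, with a fold of 12.9 and a pileup of 53 reads. The nearest replicate 1 summit was 12473 bp away. In replicate 1 the strongest was on chromosome 2 at 43567 to 44309, with a fold of 10.1 and 39 reads.

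**Figure D1:**
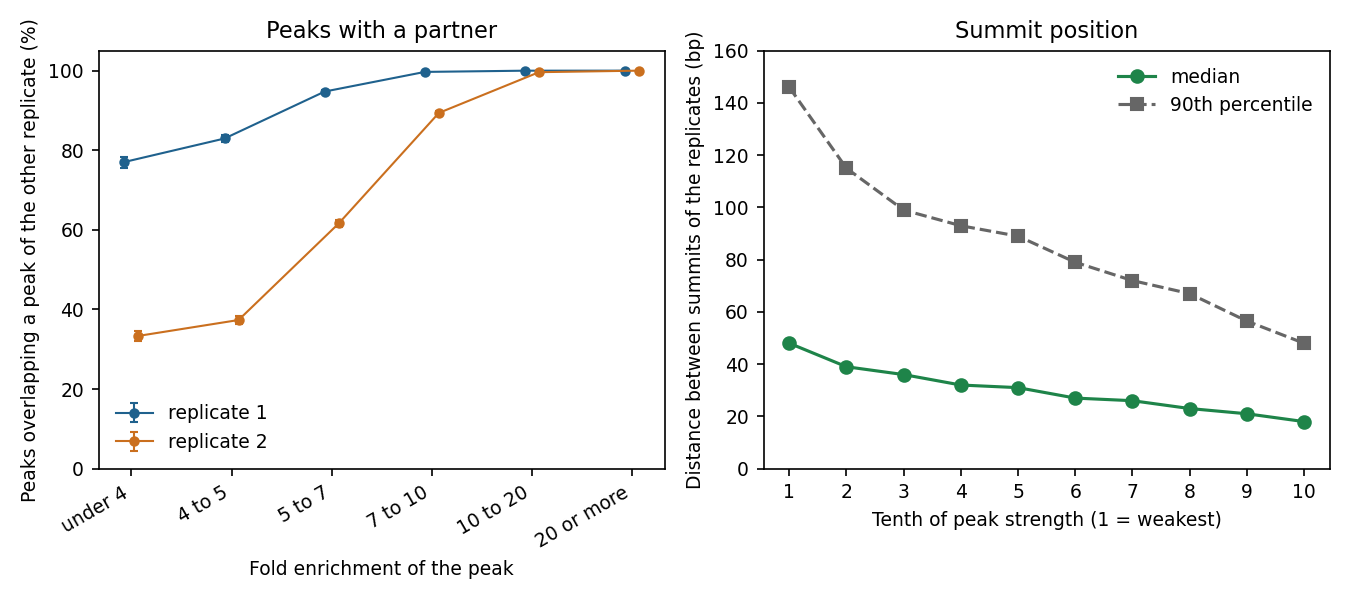
Left, share of peaks (%) that overlap a peak of the other replicate, by fold enrichment of the peak, with 95% Wilson intervals; right, distance in bp between the summits of both replicates in 10 steps of peak strength with equal numbers of peaks, as median and 90th percentile. Weak replicate 2 peaks often lack a partner, with 33.3% matched below a fold of 4, while the median summit distance falls from 48 bp in the weakest step to 18 bp in the strongest.

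Fold enrichment at reproducible peaks was higher in replicate 2. The median ratio of replicate 2 over replicate 1 was 1.27, or 0.34 on the log2 scale (95% bootstrap interval 0.33 to 0.34), with an SD of 0.43 across 44959 peaks. Replicate 2 was higher at 78.4% of them, and the median absolute log2 ratio was 0.39. Across peaks, Spearman's rho of the fold enrichments was 0.819 (0.815 to 0.822) and Pearson's r of their log2 values was 0.856. Reproducible peaks were also ranked by fold enrichment in each replicate, a value that carries the spread of the background too. Of the 100 highest in each replicate, 43 were shared. Of the highest 1000, 663 were shared, and of the highest 10000, 8003, shares that rise with the length of the list by chance as well. The SD of the log2 ratio was 0.34 in the strongest 10% of peaks and 0.44 in the weakest 10%. Summits of both replicates lay a median of 28 bp apart, and 92.4% lay within 100 bp.

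**Figure D2:**
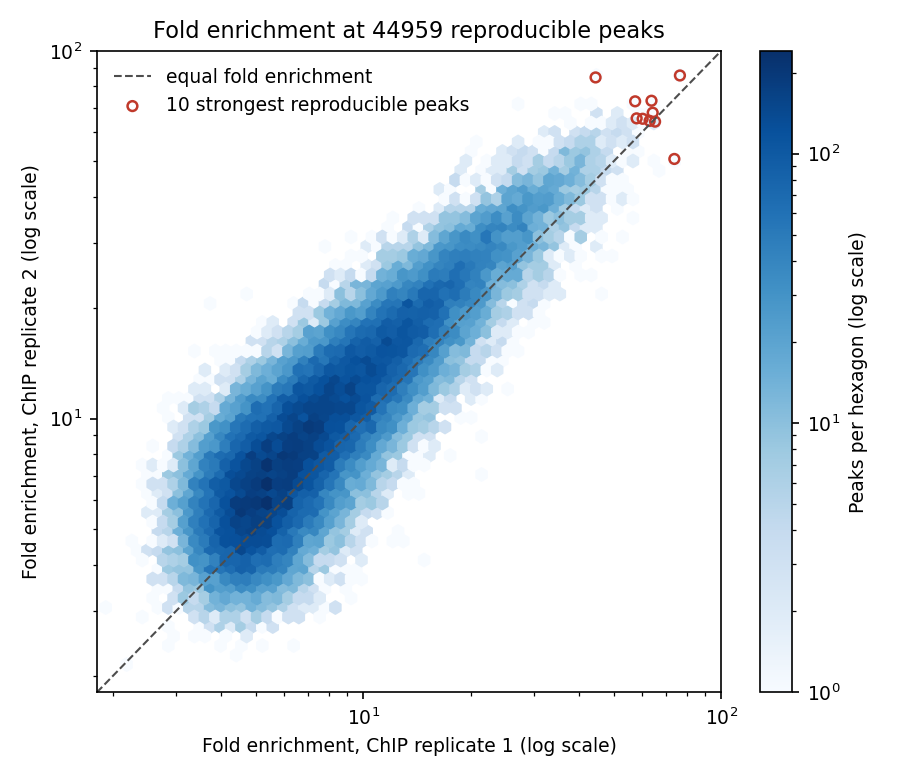
Fold enrichment over background in ChIP replicate 1 (x axis) and replicate 2 (y axis) at the 44959 reproducible peaks, both on log scales; the colour of each hexagon gives the number of peaks, the dashed line marks equal values, and circles mark the 10 strongest peaks. Most peaks lie above the line, with a median ratio of 1.27.

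Summit pileups were 1.25 times as high in replicate 2, summed over reproducible peaks. The ratio was not the same at all strengths, with 1.08 in the weakest 10% of peaks, 1.29 at strengths of 9.21 to 10.9, and 1.24 in the strongest 10%. Weak pairs entered only if called in both lists. The lower ratio there therefore does not show a smaller difference at weak sites. After scaling by the overall ratio, 13 of 44959 peaks differed between replicates at an adjusted p of at most 0.05 (exact binomial test, Benjamini-Hochberg), and 1517 at an unadjusted p of at most 0.05. The dispersion over counting was 0.943 over all reproducible peaks. Each step of 10% of the peaks was then scaled by its own ratio, so level differences between steps count in the overall value only. The dispersion was 0.579, 0.741 and 0.860 (SE 0.021 each) in the weakest steps, up to a strength of 6.12. It was between 0.962 and 1.03 in the others. In the strongest step, with a strength of 18.7 or more and median pileups of 99 and 124 reads, it was 0.977. A chi-square test of these 4496 peaks against counting error gave p = 0.857. The level itself differed, so both libraries were kept as separate replicates.

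The 10 strongest reproducible peaks lay on 8 chromosomes. The strongest was on chromosome 16 at 13050103 to 13051118, the part shared by both lists, and ranked first in both replicates. Its fold enrichment was 76.6 in replicate 1 (95% counting interval 68.3 to 85.7, 304 reads) and 85.7 in replicate 2 (76.7 to 95.4, 327 reads). The next was on chromosome 5 at 7031422 to 7032335, with folds of 63.8 (56.2 to 72.2) and 73.1 (64.8 to 82.2). The third was on chromosome 18 at 52462824 to 52463793, with folds of 64.3 and 67.8. A second site on chromosome 5, at 24777742 to 24778668, had folds of 65.3 and 64.2. The site on chromosome 1 at 8126601 to 8127933 had folds of 57.5 and 72.9. The site on chromosome 2 at 11675980 to 11677313 had folds of 63.1 and 64.5. Chromosome 8 had a site at 39326741 to 39327625 with folds of 58.0 and 65.5.

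Chromosome 13 held 2 of the 10 strongest sites, 33.3 kb apart from summit to summit. The first, at 31605606 to 31606380, had folds of 60.3 and 65.3. The second, at 31638862 to 31639582, had a fold of 73.9 in replicate 1 (66.0 to 82.6) and 50.8 in replicate 2 (45.4 to 56.7). Its pileups were 310 and 317 reads, and its local background was 3.21 reads in replicate 1 and 5.26 reads in replicate 2. The remaining site, on chromosome 9 at 47196973 to 47198205, had a fold of 44.5 in replicate 1 (39.6 to 49.9) and 84.6 in replicate 2 (75.7 to 94.3). Its pileups were 291 and 323 reads over local backgrounds of 5.56 and 2.83 reads. The fold ranks of these last 2 sites differed more between replicates than their read pileups did. The intervals leave out the counting error of the background. Their gap between replicates therefore does not show a difference beyond counting error.

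The third comparison was between regions of the genome. Reproducible peaks were concentrated towards chromosome ends. The outer 40% of the chromosomes, 20% of the span at each end, held 30724 peaks (68.7%), and the middle 20% held 2705 (6.05%). Per Mb, the outer parts had 5.68 times as many peaks as the middle. The value was 5.75 with replicate 1 alone and 5.60 with replicate 2 alone. The outer parts were denser on 19 of 20 chromosomes (exact sign test, two-sided p = 4.01e-05). These regions were chosen after the data were seen. No correction was made for how readily reads align or for gene content along the chromosomes. The ratio by itself therefore does not show a preference of the protein.

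Chromosome 4 showed the steepest contrast, with 87.9 peaks per Mb in the outer parts and 3.92 in the middle. Chromosome 13 was the exception, with 60.6 and 92.3 peaks per Mb. There the sparse zone lay near the start of the chromosome, and the longest interval without a reproducible summit ran from 3068505 to 4627551. On chromosome 20 such an interval ran from 13737203 to 16566986, which at 2.83 Mb was the longest of any chromosome. Peaks of the middle were not weaker, with a pooled median strength of 7.90 in both the outer parts and the middle. Of the 2705 pooled middle peaks, 846 lay on chromosome 13, whose middle was not sparse. The outer median was the higher one on 10 of 20 chromosomes (exact sign test, two-sided p = 1).

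**Figure D3:**
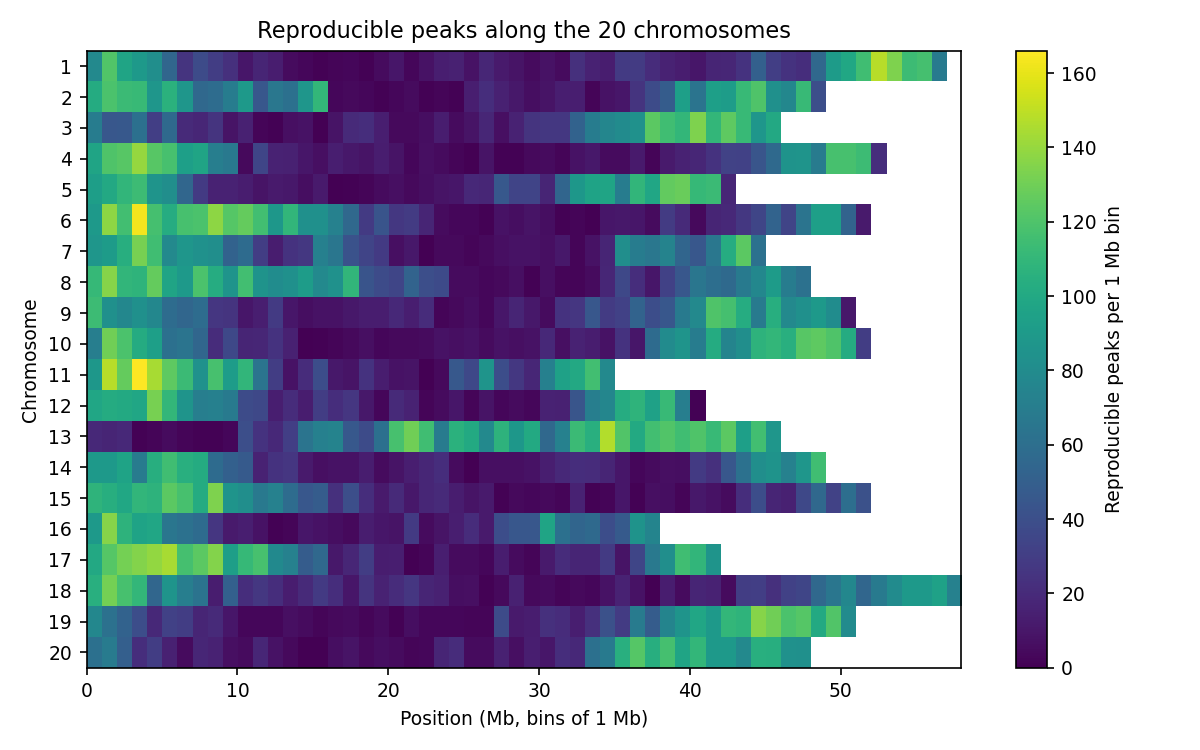
Number of reproducible peaks in each 1 Mb bin (colour) along the 20 chromosomes (rows), with position in Mb on the x axis and white beyond the last peak. Bins near chromosome ends are densest, up to 166 peaks on chromosome 11, while the sparse zone of chromosome 13 lies near its start.

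Chromosomes also differed in overall density. Chromosome 13 carried the most reproducible peaks, 3273, or 71.4 per Mb of span (95% Poisson interval 69.0 to 73.9). Chromosome 11 followed with 65.5 per Mb (62.8 to 68.2). Chromosome 18 had the lowest density, 36.6 per Mb (35.1 to 38.2), and chromosome 1 had 37.2 (35.6 to 38.8). The mean over all chromosomes was 47.2 per Mb. The ratio of replicate 2 to replicate 1 peaks ranged from 1.26 on chromosome 13 to 1.36 on chromosome 16. Among 956 bins of 1 Mb, the densest 239 held 58.1% of the summits and the sparsest 239 held 2.39%. Across bins, peak numbers of the replicates had a Spearman's rho of 0.995. The densest bin, on chromosome 11 from 3000001 to 4000000, held 166 reproducible peaks, from 181 in replicate 1 and 209 in replicate 2. A bin on chromosome 6 from 3000001 to 4000000 held 163.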

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

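The tests in this part were chosen only after the patterns were seen. Of these, the one by peak width, which replaced a simulation with an assumed peak shape, was set before its own result was seen, and the others after. The local background, inferred to come from the input samples and used above only as a divisor, carried a signal of its own. At 33 reproducible peaks it was at least 3 times the genome-wide level in both replicates. Chromosome 13 held 17 of them (51.5%), against 7.28% of all reproducible peaks. A cluster of 13 ran from 38798944 to 38856898 on chromosome 13, with backgrounds of 3.35 to 6.99 times the genome-wide level, and a cluster of 4 from 43725374 to 43740361 on chromosome 19. The highest background was on chromosome 12 at 39197258, at 35.7 reads in replicate 1 and 33.1 reads in replicate 2, where the fold enrichment was 1.91 and 3.11. Counting noise in the control reads is argued against, because raised backgrounds coincided 582 times as often as independent ones would. The sites had a median strength of 5.32, against 7.92 at peaks raised in neither replicate, but a lower strength follows from choosing sites by the divisor and says nothing about the origin of the background. Their median summit pileups were 67 reads in replicate 1 and 74 in replicate 2, against 31 and 40 at those other peaks. A peak over a raised background needs more reads to be called, so these pileups do not decide the origin either. Sequence present in more copies than the reference holds may account for the raised background, and without a genome search that stays open. No biological explanation was tested.

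Scaffolds outside the 20 chromosomes, left out of the regional comparison, held 239 reproducible peaks on 47 scaffolds. Their median strength was 7.81. Scaffold 21 held 80 of them and scaffold 28 held 35, while 15 peaks on scaffold 27 had a median strength of 14.6.

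Replicate 2 had 29.4% more peaks than replicate 1. First versions of the tests of read number and enrichment, over whole lists, hardly lowered the count. Thinning replicate 2 to the replicate 1 read number kept 99.9% of it, and scaling its excess over background down 1.32-fold, the ratio in the strongest 10% of shared peaks, left 60750 peaks. The tests were then repeated on peaks with a −log10 p of at least 15, a threshold chosen afterwards, of which replicate 1 had 28347 and replicate 2 had 38410. Thinning left 36391, which argues against read number, and the inferred input-to-ChIP depth of replicate 2 was 0.968 times that of replicate 1, which argues against a shallow input. The scaling left 28880, but its factor was measured on strong shared peaks, so a match at strong peaks restates the difference in fold enrichment and does not test it. Stronger enrichment in replicate 2 therefore stays open, as does the surplus of weak peaks, where the scaling left 114% of the replicate 1 number at a threshold of 6. Reads were extended to 250 bp in replicate 1 and 220 bp in replicate 2, and none of these tests separated that difference.

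Samples described as biological replicates showed hardly any spread beyond counting error in the summit pileups of strong peaks. That reading takes reads as independent, and how duplicate reads were treated was not examined here. In the strongest 10% of shared peaks, fold enrichment was 1.29 times as high in replicate 2. This argues against a single library, processed alike, deposited under both names. The lists differed in fragment length, 250 bp and 220 bp, and the test did not allow for that. A restriction to peaks called in both lists is consistent with the low dispersion of weak peaks, 0.579 in the weakest 10%, but it is argued against for the strongest 10%, where the dispersion was 0.977 and no peak of either list lacked a partner. If taking the highest pileup hid variation, wide peaks would show less of it. The dispersion was 0.922 in the narrowest 1499 of these strong peaks, 0.899 in the middle 1498 and 0.971 in the widest 1499 (SE 0.0365 each). Each group was scaled by its own ratio, so level differences between widths count in the 0.977 only. The narrowest and middle groups lay below 1 by more than their SE, so 1 may not be the right reference for summit pileups. The widest lay 0.0492 ± 0.0517 (SE) above the narrowest. Width rose with fold enrichment, with a rho of 0.736 in replicate 1 and 0.741 in replicate 2, and the width groups were not matched for pileup. The comparison therefore cannot decide whether the highest pileup hid variation, and that stays open. Libraries made from one batch of chromatin may account for the pattern at strong peaks, as may embryos grown alike, and both remain untested.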

How the results depend on the processing

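Leaving aside settings that cannot change a value and the strengths of the 10 named peaks, 36 values were recomputed under alternatives. None reversed. Apart from the overlap shares, which were judged by their test against chance, 8 moved beyond their spread or, for counts, by over 1.5 times. An irreproducible discovery rate of at most 0.05 kept 26117 of 44959 pairs, with Spearman's rho of 0.805, a dispersion over counting of 0.835, a median log2 ratio of 0.38 and a median summit distance of 24 bp. It selects pairs of similar rank by construction, and beyond that the cause was not tested. Requiring summits within 100 bp, added after the data were seen, gave 41530 pairs, a rho of 0.825, a median log2 ratio of 0.35 and a median summit distance of 26 bp. The peak number was 43450 at q of at most 1e-5, 43664 at 50% reciprocal overlap, and 48191 to 62340 with either replicate alone. No q threshold changed nothing, since every deposited peak had passed 0.01. The overlap shares stayed above chance under every alternative run, but their size moved beyond the Wilson intervals, to 84.9% of replicate 1 and 85.3% of replicate 2 peaks with equal numbers of top peaks, and to 90.6% and 70.04% at 50% reciprocal overlap. The outer-to-middle density ratio was 5.60 to 5.75 with either replicate alone and lay between these values at q of at most 1e-5, 50% reciprocal overlap, the irreproducible discovery rate and summits within 100 bp. It was not computed with equal numbers of top peaks. With a single replicate, the strength of the site on chromosome 9 went from 61.4 to 44.5 or 84.6. Of the 10 strongest peaks, 9 stayed in every alternative list of pairs, and the second site on chromosome 13 was lost at 50% reciprocal overlap because replicate 1 had a longer peak there. No paired analysis was possible because no file of the input samples was used, and the peak lists compare each ChIP library with its background by themselves. The promoter, G-box, bound-gene and gene-list results and their alternatives were not run, for want of a genome and annotation of the build. At the weak end of the lists, pileups of 11 or 12 reads stand over a background of about 3 reads. Whether depth limits these peaks was not tested.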

Other observations

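The densest 50 kb stretch was on chromosome 17, where 22 reproducible summits lay between 5282923 and 5331957, with a median strength of 6.40 and a highest of 36.9. Stretches on chromosomes 6, 12, 13 and 17 held 18 each. They were picked for their density, and no chance level was computed for them. The one on chromosome 13, from 34652831 to 34700691, had a median strength of 10.7, and the one on chromosome 12, from 3416534 to 3463576, of 10.6. Of the 66 sites with a strength of 50 or more, 3 pairs lay within 50 kb of each other. Besides the pair on chromosome 13, these were 8097570 and 8127397 on chromosome 1, with strengths of 55.6 and 64.7, and 39563630 and 39597804 on chromosome 12, with 54.3 and 59.7.

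Both hypotheses on neighbouring sites had their tests set before the results were seen. The first was that sites cluster beyond their regional density. Neighbouring summits up to 2 kb apart numbered 8437, against a mean of 7289 and at most 7451 in 100 sets in which each site was moved at random within 50 kb, a ratio of 1.16. The excess lay between 1 and 2 kb, with 5632 pairs against a mean of 3447. Under 1 kb there were 2805 pairs, fewer than the moved sets held on average. Moved sites could lie at any distance, while the closest reproducible peaks lay 237 bp apart. The moved sets thus lack the minimum spacing of called peaks, which may shift pairs from under 1 kb to between 1 and 2 kb. The total up to 2 kb goes with a modest clustering, but 1 broad site called as 2 peaks may add to it. Neither that nor the spacing was separated here. The second was that strong sites lie next to strong sites. Spearman's rho between neighbours up to 10 kb apart was 0.00805 over 26888 pairs, with a one-sided permutation p of 0.152 from 1000 permutations within 1 Mb bins, so the test over all these pairs did not pass. By distance, rho was -0.0386 up to 1 kb, 0.0372 from 1 to 2 kb, 0.0169 from 2 to 5 kb and -0.0125 from 5 to 10 kb, and these bands were not tested separately. Between replicate 1 at one site and replicate 2 at the next, rho was 0.00756, with a permutation p of 0.170.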
